A study of Homo sapiens with 24 samples.

How the data were processed

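Gene expression was measured on 24 Affymetrix whole-transcript arrays, 1 per well of cultured human cells. Nthy-ori 3-1 is a line of normal thyroid follicular cells immortalised with SV40, and TPC-1 is a line from a papillary thyroid carcinoma. Per the labels' protocols, cells were transfected with 20 nM of siRNA using a lipid reagent, and total RNA was collected 48 h or 72 h later, extracted with a column kit and labelled with biotin. The COPZ1 reagent (siCOPZ1) is an esiRNA, a pool of short duplexes cut enzymatically from a longer double-stranded RNA, whereas the non-targeting control (siNT) is a single synthetic duplex. The kind of reagent therefore changes together with the depletion in every comparison of siCOPZ1 with siNT. The labels give DMEM as the medium of TPC-1 and RPMI medium as that of Nthy-ori 3-1, so line and medium also change together.

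The deposited table holds 1 log2 expression value per Ensembl gene and array, and the range of 1.70 to 14.2 without negative values fits the log2 unit. RMA, which combines background correction, quantile normalisation between arrays and a summary over probes, is named in the submitters' processing notes. The chip type, the probe set definition, the software version and the genome build are not given in the sources used here, so no coordinates are printed. The scanner files were not used here. RMA forces the arrays towards one distribution, so a change shared by most genes would be removed before any comparison, and its probe summary compresses changes of dim genes towards 0.

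The table has 18637 genes. Spreadsheet software had turned 28 symbols into dates, and these genes were kept under their Ensembl identifiers. For 5 symbols that stood on more than 1 line, the line with the higher mean over all arrays was kept, which left 18632 genes tested. Of 18604 symbols, 17554 matched a current symbol in the RefSeq gene table of assembly GRCh38.p14, which was used only for names.

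The 24 arrays fall into 8 groups of 3 by line, siRNA and time. One linear model with a mean for each group was fitted to all arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with default settings), and 11 contrasts were taken from it, all tested two-sided. These were siCOPZ1 minus siNT in each line at each time, the difference of that effect between the lines at each time, its difference between the times in each line, TPC-1 minus Nthy-ori 3-1 with siNT over both times, and 72 h minus 48 h with siNT in each line. P values were adjusted by Benjamini and Hochberg within each contrast, and a gene was called at an adjusted p below 0.05. At an unadjusted p below 0.05, a share of 0.05 of the genes would be due to pass if none had changed. One spread per gene is shared by all groups, although the median residual standard deviation was 0.206 in Nthy-ori 3-1 and 0.250 in TPC-1. A count below that share therefore does not show that no gene changed. COPZ1 was also compared by an exact permutation test of 3 against 3 wells.

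A set of 15 gene lists with 538 members, of which 535 were found, was tested with camera in limma at a preset correlation between genes of 0.01, with adjustment over the 15 lists in 6 contrasts. They cover interferon-stimulated genes, nucleic acid sensing, antigen processing, inflammatory and NF-kB genes, the integrated stress response, endoplasmic reticulum chaperones and degradation, COPI and Golgi trafficking, autophagy, the cell cycle, sterol and fatty acid synthesis, p53 and apoptosis, heat shock and danger signals, extracellular matrix, thyroid differentiation and markers of other cell types. COPZ1 belongs to none of them. Camera asks whether a list moved more than other genes. Estimating the correlation from the data and fry, which asks only whether a list moved one way, served as alternatives. Groups, contrasts, lists, tests and alternatives were fixed before the data were examined, except for 1 alternative and 5 tests that the closing section names as chosen later.

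Genes are named by a rule. In each comparison of siCOPZ1 with siNT these are COPZ1 and its paralog COPZ2, the 5 largest called rises and the 5 largest called falls among genes whose 3 siCOPZ1 and 3 siNT values do not overlap, and, from each list with at least 5 called members, the 3 with the smallest adjusted p. In the differences between lines, times and untreated backgrounds they are the 5 largest called differences in each direction, with 2 members per such list for the line differences. IFIT1, ISG15, MX1, IFNB1, CCL5, CXCL10, DDIT3, HSPA5 and HLA-B are always given. Clone-named genes were passed over, and a few genes that met the rule are not reported here. Any gene outside this rule is said to have been chosen after its values were seen.

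The labels give each array a number from 1 to 3 and call the wells triplicates. After subtraction of group means, siCOPZ1 and siNT arrays of one number correlated across genes at 0.404, 0.292 and 0.145 in TPC-1 at 48 h, the only line and time at which all 3 pairs exceeded 0.1. Elsewhere arrays of one number correlated at 0.0279 to 0.234, each above its correlation with other numbers. The number within each line was therefore used as a block in an alternative fit. Its values stand beside the TPC-1 results at 48 h and between the times. Other counts that it moved are in the closing section. The other alternatives were a mean-variance trend with robust moderation, a fit on the arrays of one contrast alone, array weights, a second quantile normalisation, centring on array medians, removal of the dimmest tertile of genes, averaging of repeated symbols, a threshold of 2-fold, and leaving out each array in turn. The number of arrays limits the precision, and the median standard error of a siCOPZ1 effect was 0.19 on the log2 scale.

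The calling step was tested on simulated values for the 18632 genes, drawn with the means and spreads of the arrays. For siCOPZ1 in TPC-1 at 72 h it recovered 22% of genes changed by 0.5, 68% of those changed by 1, 92% of those changed by 2 and 100% of those changed by 4 on the log2 scale, and called 10 unchanged genes. For the difference between the lines at 72 h the recovered shares were 4%, 44%, 80% and 100%, with 5 unchanged genes called. A list of 55 genes shifted by 0.3 was detected by camera (adjusted p = 8.19e-10), and 0 of the other 88 list tests gave a call. The simulated genes varied independently of each other, without structure by array number. The simulation therefore cannot tell how often camera calls unshifted lists whose genes are correlated. Only 50 genes at each size and the shifted list were changed, against 2692 called genes in the real TPC-1 comparison at 72 h. The adjustment depends on how many genes change, so the recovered shares may differ there. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.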

Results

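Expression profiles were collected from 24 wells, 12 of Nthy-ori 3-1 normal thyroid cells and 12 of TPC-1 papillary thyroid carcinoma cells. Each line was transfected with siCOPZ1, which targets the zeta-1 subunit of the COPI coat of Golgi vesicles, or with the non-targeting siNT, and was sampled after 48 h or 72 h, with 3 wells in each of the 8 groups. The series title names thyroid tumour cells, a type I interferon response and immunogenic cell death, so the comparisons ask which genes respond to loss of COPZ1 in each line and whether the lines respond alike. Pairs of arrays within a group correlated at 0.971 to 0.989 across genes, and the groups' median standard deviations per gene lay between 0.163 and 0.241. The first principal component, with 60.9% of the variance, separated the lines, and the second, with 7.26%, set the TPC-1 siCOPZ1 arrays at 72 h apart. On the next, with 5.05%, the array numbered 1 had the lowest score of each TPC-1 group, although in siNT at 72 h array 2 lay farther from the other arrays. The series description calls the replicates triplicate wells and does not say whether they came from separate experiments, so every p below measures only the spread between these wells.

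COPZ1 (ENSG00000111481) fell in both lines at both times. In Nthy-ori 3-1 its level with siCOPZ1 was 25.8% of that with siNT at 48 h, a log2 difference of -1.96 ± 0.23 (SE, 3 wells per group, limma adjusted p = 0.000656), and 33.6% at 72 h, a difference of -1.57 ± 0.23 (adjusted p = 0.0178). In TPC-1 it was 10.5% at 48 h (-3.25 ± 0.23, adjusted p = 1.03e-07) and 22.2% at 72 h (-2.17 ± 0.23, adjusted p = 1.83e-06). All siCOPZ1 wells lay below all siNT wells in each comparison, and the exact two-sided permutation p was 0.1, the smallest that 3 wells against 3 allow. The fall was deeper in TPC-1 than in Nthy-ori 3-1 by a difference of -1.30 at 48 h (95% interval -1.96 to -0.63) and -0.60 at 72 h (-1.26 to 0.07), neither of which passed adjustment over all genes in limma (adjusted p = 1.00 and 0.371). COPZ2, which encodes the other zeta subunit, was not called in any comparison, with differences of 0.24 and 0.14 in Nthy-ori 3-1 and 0.20 and -0.22 in TPC-1. In Nthy-ori 3-1 the COPZ1 call at 72 h was lost without siNT array 1, 2 or 3 (adjusted p = 0.148, 0.115 and 0.0928) or siCOPZ1 array 2 or 3 (0.147 and 0.168), although the difference stayed between -1.43 and -1.60 in these runs. With only the 6 arrays of each comparison, neither Nthy-ori 3-1 call held (adjusted p = 0.734 at 48 h and 0.465 at 72 h).

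**Figure D1:**
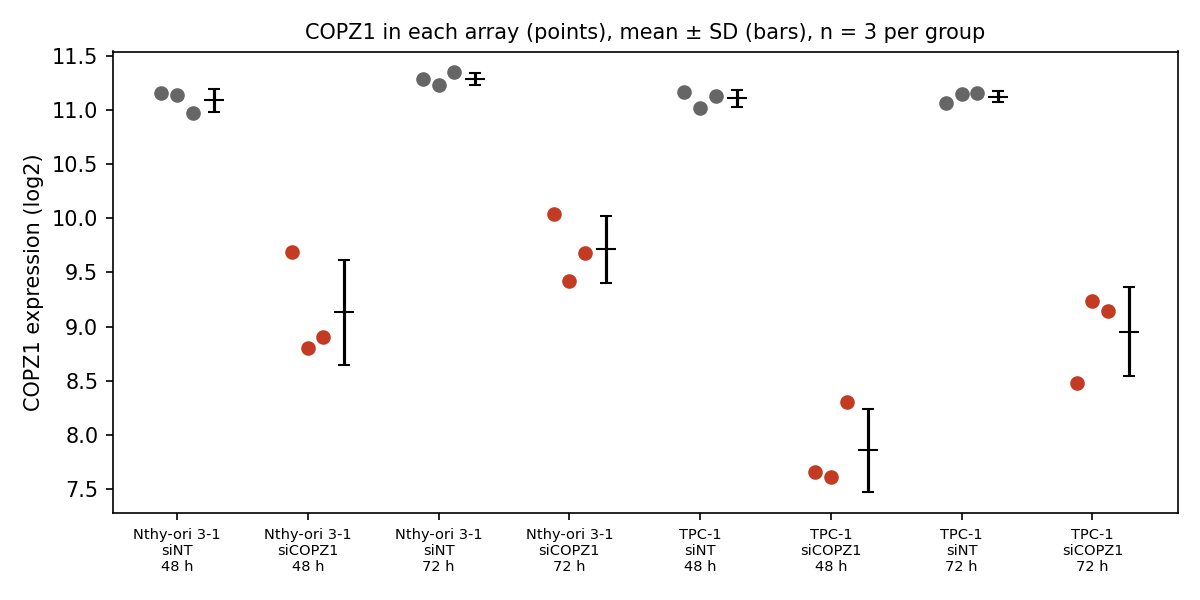
COPZ1 expression on the log2 scale in each of the 24 arrays, grouped by line, siRNA and time, with siNT in grey and siCOPZ1 in red; black bars show the mean and standard deviation of 3 wells. The siCOPZ1 means lie at 9.13 and 9.71 in Nthy-ori 3-1 and at 7.86 and 8.95 in TPC-1, and the siNT means between 11.1 and 11.3.

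In TPC-1 at 72 h, the 5 largest rises were those of a protease inhibitor, a survival factor, a hyaluronan-binding protein, a cytokine and a collagenase. SERPINB2, an inhibitor of plasminogen activators, rose by 6.61 ± 0.51 on the log2 scale (SE, 3 wells per group), which is 97.8-fold. BCL2A1, an anti-apoptotic member of the BCL2 family, rose by 5.70 ± 0.38, TNFAIP6, a hyaluronan-binding protein induced by TNF, by 5.59 ± 0.60, the cytokine IL1A by 5.27 ± 0.61 and the collagenase MMP1 by 5.25 ± 0.29. The largest falls were those of the urea transporter SLC14A1 at -4.56 ± 0.68, the organic anion transporter SLCO4C1 at -3.43 ± 0.35, the transcription factor HLF at -3.42 ± 0.22, the sulfotransferase CHST9 at -3.21 ± 0.21 and the filament-associated protein FLG at -3.10 ± 0.16. In limma, 2692 of 18632 genes (14.4%) were called, 1310 higher and 1382 lower, and 887 of them differed at least 2-fold, 401 higher and 486 lower. With only the 6 arrays of this comparison in the fit the count was 1507, of which 1438 were among the 2692. Median centring of the arrays, which left the count within 1.5-fold, put 55.3% of the called genes on the higher side in place of 48.7%.

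The list of inflammatory cytokines and NF-kB targets rose most in these cells, with 28 of its 34 members called higher, 1 called lower and a median of 1.85. Among the 28 were the chemokines CCL20 at 4.10 ± 0.31 and CXCL5 at 1.99 ± 0.19 and the signalling adaptor TRAF1 at 4.26 ± 0.41, while the member called lower, chosen for mention after its value was seen, was the chemokine CX3CL1 at -2.00. Of 39 genes of the integrated stress response, through which ATF4 raises amino acid metabolism and the death-related factor DDIT3, 22 rose and none of the other 17 was called; ALDH1L2 rose by 2.46 ± 0.23, STC2 by 2.34 ± 0.26, DDIT3 by 2.01 ± 0.30 and CEBPG by 1.49 ± 0.20. Of 40 chaperone and degradation genes of the endoplasmic reticulum, 26 rose and 1 fell, with VIMP at 1.67 ± 0.16, MANF at 1.05 ± 0.12, DNAJC3 at 0.84 ± 0.10 and the chaperone HSPA5 at 0.79 ± 0.10. Of 42 genes of the COPI coat and Golgi trafficking, 20 rose and 3 fell, with the Golgi tether GOLGA2 at 0.82 ± 0.13, the SNARE YKT6 at 0.83 ± 0.14 and the membrane-bound factor CREB3 at 0.83 ± 0.14. The 3 that fell, chosen after their values were seen, were the coat subunit COPG2 (-0.97), ARFGAP2 (-0.45) and RAB1B (-0.43). Adjusted over the list alone, 30, 26, 28 and 29 members of these lists were called. Camera gave adjusted p = 2.04e-24 for the inflammatory list, 4.60e-14 for both stress lists and 1.85e-07 for the COPI list. With an estimated correlation the inflammatory, endoplasmic reticulum and COPI lists still passed (adjusted p = 0.0231, 0.00191 and 0.0231), and the integrated stress response did not (adjusted p = 0.0712).

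**Figure D2:**
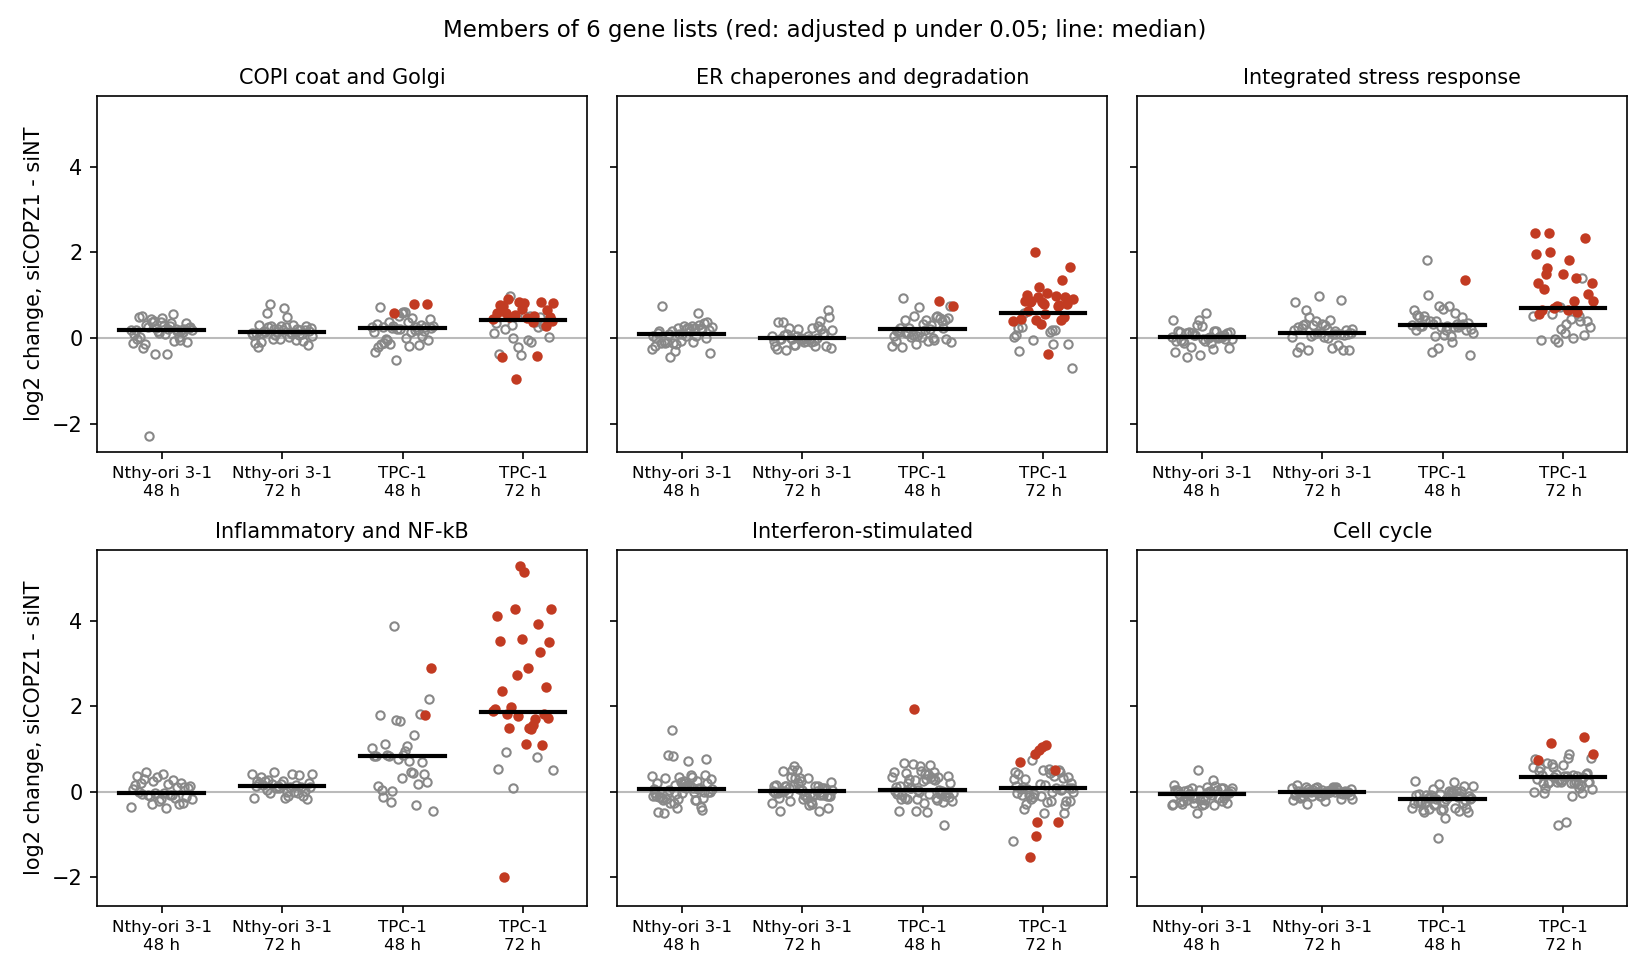
Log2 change (siCOPZ1 minus siNT) of each measured member of 6 gene lists in the 4 comparisons; red points passed an adjusted p of 0.05, grey points did not, and black lines mark medians. In TPC-1 at 72 h the inflammatory list has a median of 1.85 and 28 called rises, whereas the interferon-stimulated list has a median of 0.09 with 6 called rises and 4 called falls.

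Interferon-stimulated genes of TPC-1 at 72 h moved in both directions. Of 55 measured, 6 rose, 4 fell and 45 were not called, with 11 called when adjusted over the list alone. PARP12 (0.52 ± 0.11), the exonuclease ISG20 (1.09 ± 0.27) and the transcription factor IRF1 (1.05 ± 0.26) were among those that rose, whereas IFIT1, which binds viral RNA, fell by 1.04 on the log2 scale. The other called members, chosen after their values were seen, were IFIT3 (0.98), IFIH1 (0.88) and DDX60L (0.69) on the higher side and IFI27 (-1.51), IFIT2 (-0.72) and PARP9 (-0.71) on the lower side. ISG15 (0.16), MX1 (0.52), IFNB1, the gene of interferon beta (0.30), CCL5 (0.52), CXCL10 (0.46) and HLA-B (0.12) were not called. The list as a whole did not move one way in camera (adjusted p = 0.258, median 0.09). Of 29 genes of nucleic acid sensing and interferon ligands, 4 rose, namely the receptor IFNAR2 (1.23), TRAF3 (0.74), TRIM25 (0.59) and MB21D1 (0.85), again chosen after their values were seen. The list itself was not called in camera (adjusted p = 0.110) and was called up in fry (0.0132). Of 22 genes of antigen processing, 3 rose and the list was not called (adjusted p = 0.120). Of all 18632 genes 14.4% were called in this comparison, 1310 higher and 1382 lower. The called shares of the nucleic acid and antigen lists, all rises, were larger than the share of all genes called higher, with 4 and 3 genes. That of the interferon-stimulated list, in both directions, lay slightly above 14.4%. The IFIT1 call was lost without siNT array 1, 2 or 3 (adjusted p = 0.0827, 0.0958 and 0.0756) and without siCOPZ1 array 2 (0.251, with the change at -0.51), that of IRF1 without the arrays numbered 1, an alternative chosen after seeing the data, and CCL5 (adjusted p = 0.0564) passed in 4 of its 15 alternatives, among them the run without siNT array 3 (0.0476). CXCL10 (adjusted p = 0.146) passed in 1 of 14, the run without siCOPZ1 array 2 (0.0477). The antigen list passed without siNT array 1 (adjusted p = 0.0331) or siCOPZ1 array 3 (0.0489).

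Other lists in TPC-1 at 72 h held called members in smaller numbers, beside 14.4% of all 18632 genes called in this comparison, 1310 higher and 1382 lower. The thyroid list, with falls alone, had a larger called share than all genes called lower. The other-cell list, with falls alone, and the cell cycle list, with rises alone, lay near the share of all genes called in their direction. Of 34 genes of cholesterol and fatty acid synthesis, 7 fell and 0 rose, with the desaturase SCD at -1.12 ± 0.20, the elongase ELOVL6 at -1.08 ± 0.22 and the carboxylase ACACA at -0.60 ± 0.13. In the heat shock and danger signal list, 5 of 25 genes rose and 1 fell, with the channel PANX1 at 1.13 ± 0.11, the haem oxygenase HMOX1 at 2.07 ± 0.34 and the small heat shock protein HSPB1 at -0.74 ± 0.10. Apoptosis and p53 genes split into 10 that rose and 5 that fell of 35, with the death receptors TNFRSF10A and TNFRSF10B at 1.00 ± 0.17 and 1.00 ± 0.18. Matrix and mesenchymal genes split into 10 and 6 of 40, with MMP9 at 1.86 ± 0.18 and the urokinase receptor PLAUR at 1.61 ± 0.19, and autophagy genes into 7 and 3 of 42, with WIPI1 at 1.02 ± 0.18, ATG7 at 0.89 ± 0.17 and the lysosomal regulator TFEB at -0.94 ± 0.23. Of 20 thyroid differentiation genes 3 fell, and of 29 markers of other cell types 2 fell, with none of either list called higher. Of 49 cell cycle genes 4 were higher than in siNT, among them CDC6 (1.13), UBE2C (0.89) and BRCA1 (0.74), chosen after their values were seen. Over the same interval the cell cycle list of the siNT wells had itself dropped, as given with the change over time below. Adjusted over the list alone, 8 lipid synthesis, 6 heat shock, 18 apoptosis, 20 matrix, 11 autophagy, 3 thyroid, 1 other-cell and 3 cell cycle genes were called. Camera called lipid synthesis down (adjusted p = 0.000650) and heat shock and the cell cycle up (adjusted p = 0.0349 and 0.000435), and with an estimated correlation these gave adjusted p = 0.502, 0.448 and 0.770. It did not call the apoptosis, matrix, autophagy, thyroid or other-cell lists (adjusted p = 0.349, 0.106, 0.524, 0.171 and 0.547), of which fry called the matrix list up (0.0279) and the thyroid list down (0.0429). The cell cycle call was lost without siNT array 1 (adjusted p = 0.107), and the heat shock call without siNT array 2 or 3 (0.0694 and 0.0604) or siCOPZ1 array 2 (0.0684).

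At 48 h in TPC-1, the response was smaller but already held inflammatory and Golgi genes. TRAF1 rose by 2.89 ± 0.41 on the log2 scale, BCL2A1 by 2.68 ± 0.38, the interferon-inducible IFI6 by 1.93 ± 0.35, MMP1 by 1.81 ± 0.29 and the cytokine TNF by 1.79 ± 0.34 (SE, 3 wells per group). Besides COPZ1, falls were called for TMEM56-RWDD3 (-2.31 ± 0.42), LRRC34 (-1.08 ± 0.20), the iron-binding nuclear protein PIR (-0.996 ± 0.20) and the kinase MAP2K6 (-0.81 ± 0.16). Chosen after their values were seen, the called members of the COPI list were the coat subunit COPG1 (0.59), the retrieval receptor KDELR3 (0.80) and the cargo receptor TMED3 (0.79), those of the endoplasmic reticulum list were XBP1 (0.74) and SEC24D (0.87), and STC2 (1.36) and HMOX1 (1.67) were called in the integrated stress and heat shock lists. None of IFIT1 (-0.44), ISG15 (0.41), MX1 (0.41), IFNB1 (-0.09), CCL5 (0.13), CXCL10 (0.02), DDIT3 (0.39), HSPA5 (0.33) and HLA-B (0.29) was called.

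In limma, 31 genes were called in TPC-1 at 48 h, 25 higher and 6 lower, of which 14 differed at least 2-fold, and 25 of the 31 were called in the same direction at 72 h and 0 in the opposite one. Camera called the inflammatory, integrated stress, endoplasmic reticulum and COPI lists up (adjusted p = 8.74e-14, 5.62e-08, 1.55e-08 and 1.66e-09, medians 0.83, 0.31, 0.21 and 0.23). Adjusted over the list alone, 17, 2, 11 and 13 of their members were called. With an estimated correlation the endoplasmic reticulum and COPI lists passed (adjusted p = 0.0110 and 0.0143) and the inflammatory and integrated stress lists did not (adjusted p = 0.114 and 0.260). The matrix and antigen lists were called up (adjusted p = 0.00185 and 0.0184) and the cell cycle down (adjusted p = 0.00280), but with an estimated correlation all 3 calls ended (adjusted p = 0.383, 0.542 and 0.770). The interferon-stimulated list was not called (adjusted p = 0.171), except without siCOPZ1 array 3 (0.0387). With the array number as a block 78 genes were called, 28 of them among the 31, while MAP2K6 lost its call (adjusted p = 0.0531). The count was 14, 12 and 8 without siNT array 1, 2 or 3, 9 and 6 without siCOPZ1 array 1 or 2, and 38 without siCOPZ1 array 3. Of the 10 called genes that the naming rule gives here, COPZ1, TRAF1 and BCL2A1 passed whichever 1 array was left out, and the other 7 each lost the call in at least 3 of the 6 runs. TRAF1 and BCL2A1 lost their calls without all arrays numbered 1, a fit chosen after seeing the data (adjusted p = 0.160 for both). They also lost them with only the 6 arrays of this comparison (0.516 and 0.548). PIR (adjusted p = 0.0472) lost its call with median centring as well. Without siNT array 2 the cell cycle list turned up (adjusted p = 0.802) and the matrix call ended (0.0505), without siCOPZ1 array 1 the cell cycle list again turned up (0.285), and without siNT array 3 it was not called (0.274). These runs break pairs of one number, within which the cell cycle mean was lower with siCOPZ1 in all 3 (9.05 against 9.16, 9.89 against 10.2 and 9.79 against 9.94). The antigen call ended without siNT array 2 or 3 (0.0954 and 0.252) or siCOPZ1 array 1 (0.165). With only the 6 arrays of this comparison, 1 gene was called, and with the dimmest tertile of genes left out 56.

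In Nthy-ori 3-1, COPZ1 was the only gene called at either time, and the clearest group change was a small rise of the COPI and Golgi list. Its median was 0.19 at 48 h and 0.15 at 72 h, and camera called it up at both times (adjusted p = 2.82e-08 and 2.82e-08), also with an estimated correlation (adjusted p = 0.0190 and 0.0190). None of its 42 members was called over all genes, while 5 were called at 48 h and 1 at 72 h when adjusted over the list alone. Chosen after their values were seen, KDELR3 differed by 0.57, COPB2 by 0.45, COPG1 by 0.41, GOLGA2 by 0.47 and KDELR2 by 0.34 at 48 h, and GOLGA5 by 0.69 at 72 h. The inflammatory list, by contrast, had medians of -0.02 and 0.13 and was not called (adjusted p = 0.771 and 0.106). At 72 h it passed without siCOPZ1 array 1 (0.0349) and without all arrays numbered 1 (0.00194), over a range up to 0.818 in its alternatives. Nor was the interferon-stimulated list (adjusted p = 0.432 and 0.575). None of the always-named genes was called, with DDIT3 at 0.14 and 0.50, HSPA5 at 0.09 and -0.01, IFIT1 at 0.16 and 0.33, ISG15 at 0.25 and -0.08, MX1 at 0.16 and 0.32, IFNB1 at 0.03 and 0.03, CCL5 at 0.37 and 0.25, CXCL10 at 0.07 and 0.13 and HLA-B at 0.25 and -0.19 at 48 h and 72 h. At an unadjusted p below 0.05, 906 genes passed in limma at 48 h and 574 at 72 h. Both lay under the share due with no change, which does not show that no gene changed.

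Camera also called lipid synthesis (adjusted p = 0.000548, median 0.21) and endoplasmic reticulum genes (0.0151, median 0.10) up at 48 h and the integrated stress response up at 72 h (0.000885, median 0.12) in Nthy-ori 3-1. With an estimated correlation these gave adjusted p = 0.498, 0.287 and 0.542, and none of their members was called. Leaving out siNT array 2 or siCOPZ1 array 3 ended the lipid call (adjusted p = 0.181 and 0.103), and siNT array 3 or siCOPZ1 array 3 the endoplasmic reticulum call (0.0688 and 0.0744). Without siNT array 2 at 72 h the integrated stress list turned down (0.646), and without siNT array 1 the interferon-stimulated list was called up (0.0129). The lipid list, not called at 72 h (0.0765), was called up without siNT array 3 (0.000770) or siCOPZ1 array 1 or 2 (0.00574 and 0.00177).

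The siCOPZ1 effects of the lines were compared gene by gene, although COPZ1 alone was called in Nthy-ori 3-1. At 72 h the siCOPZ1 effect was larger in TPC-1 for SERPINB2 (difference of effects 6.92 ± 0.72 on the log2 scale), TNFAIP6 (5.65 ± 0.86), BCL2A1 (5.34 ± 0.54), IL1A (5.18 ± 0.86) and MMP1 (4.92 ± 0.41), and more negative in TPC-1 for SLC14A1 (-4.66 ± 0.96), SLCO4C1 (-3.40 ± 0.50), HLF (-3.18 ± 0.31), CHST9 (-3.11 ± 0.29) and FLG (-2.95 ± 0.23). The inflammatory list differed most, with 19 members called more positive and 1 more negative in TPC-1, including CCL20 (3.97 ± 0.44) and CXCL5 (2.00 ± 0.27). Of the integrated stress list 9 members were more positive, including ALDH1L2 (2.28 ± 0.32), STC2 (2.27 ± 0.37) and DDIT3 (1.52 ± 0.42). Of the endoplasmic reticulum list 12 were, including MANF (1.12 ± 0.16) and HSPA5 (0.80 ± 0.14), and of the matrix list 6, including MMP9 (1.81 ± 0.25). The apoptosis list held 4 more positive and 3 more negative in TPC-1. Neither COPZ2 (-0.36) nor IFIT1 (-1.37), ISG15 (0.24), MX1 (0.20), IFNB1 (0.27), CCL5 (0.28), CXCL10 (0.33) or HLA-B (0.32) was called.

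In limma, 749 genes differed between the lines at 72 h, 344 more positive and 405 more negative in TPC-1, and 526 of them by at least 1 on the log2 scale. Adjusted over the list alone, 28 inflammatory, 11 integrated stress, 23 endoplasmic reticulum, 14 matrix and 10 apoptosis genes were called. Camera called the inflammatory, endoplasmic reticulum and integrated stress lists (adjusted p = 2.41e-22, 1.75e-12 and 9.11e-10) and, with smaller shifts, the COPI (0.00834), cell cycle (0.000650), matrix (0.0310) and lipid synthesis lists (4.64e-05, more negative in TPC-1). With an estimated correlation the inflammatory and endoplasmic reticulum lists passed (adjusted p = 0.0290 and 0.00201), and the integrated stress, COPI, cell cycle, matrix and lipid lists did not (adjusted p = 0.161, 0.318, 0.770, 0.542 and 0.405). The interferon-stimulated list was not called (adjusted p = 0.418). Nor were the antigen and heat shock lists (camera adjusted p = 0.0709 and 0.0521), although each was called up in 5 of the 12 runs without 1 array. The count was 485 without TPC-1 siNT array 3, 442 without the arrays numbered 1 and 1210 with array weights. DDIT3 (adjusted p = 0.0461) lost its call without any 1 of 10 of the 12 arrays, with adjusted p up to 0.143 over its alternatives. The HSPA5 call ended without the arrays numbered 1 (0.0608), and IFIT1 was called without TPC-1 siCOPZ1 array 1 (0.0360). The COPI call ended without Nthy-ori 3-1 siCOPZ1 array 1 (adjusted p = 0.0783), and that of the cell cycle without TPC-1 siNT array 1 (0.101). The matrix call ended without Nthy-ori 3-1 siNT array 2 (0.114), Nthy-ori 3-1 siCOPZ1 array 1 or 3 (0.0563 and 0.0708), TPC-1 siNT array 2 (0.0511) or TPC-1 siCOPZ1 array 1 (0.0627).

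**Figure D3:**
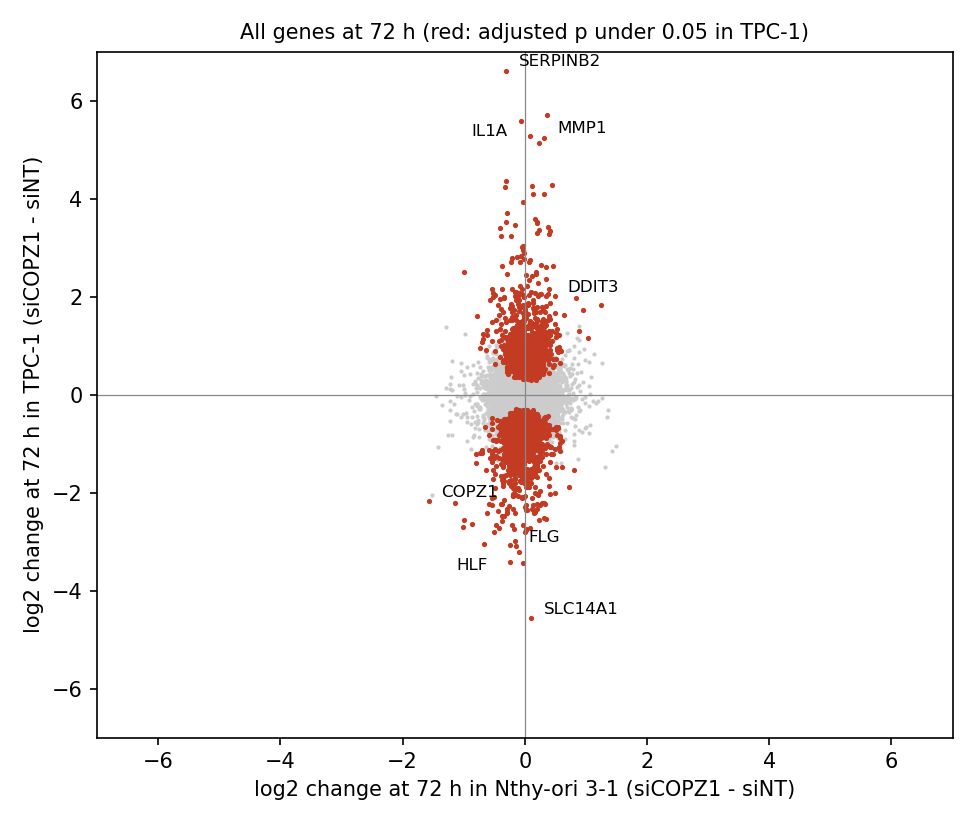
Log2 change at 72 h (siCOPZ1 minus siNT) of each of 18632 genes in Nthy-ori 3-1 (horizontal) and TPC-1 (vertical); red points were called in TPC-1 at an adjusted p below 0.05. SERPINB2 lies at 6.61 in TPC-1, and COPZ1, at -2.17 and -1.57, is the only gene called in both lines.

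At 48 h none of the genes showed a called difference between the lines, DDIT3 (0.25), HSPA5 (0.25), IFIT1 (-0.61), ISG15 (0.16), MX1 (0.26), IFNB1 (-0.11), CCL5 (-0.24), CXCL10 (-0.06), HLA-B (0.04) and COPZ2 (-0.04) included. The count was 0 in limma, and 7 without TPC-1 siCOPZ1 array 3. At an unadjusted p below 0.05 there were 615 genes, under the share due with no change. Camera nevertheless gave larger changes in TPC-1 for the inflammatory (adjusted p = 8.76e-12), integrated stress (1.26e-05), endoplasmic reticulum (0.000663) and matrix lists (0.000660) and a more negative one for lipid synthesis (0.000235). With an estimated correlation all 5 calls ended (adjusted p = 0.161, 0.386, 0.104, 0.318 and 0.462). The matrix call also ended without siNT array 2 of Nthy-ori 3-1 (0.0571) or of TPC-1 (0.0505). Across genes, which are not independent replicates, the changes of the lines correlated at r = 0.243 at 48 h (Spearman's rho 0.268) and 0.0876 at 72 h (rho 0.0956). COPZ1, the target of the siRNA, was the only gene called in both lines at either time, so the overlap shows no agreement beyond the target. Independent lists would share 0.000322 falling genes at 48 h and 0.0742 at 72 h.

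Between 48 h and 72 h, the siCOPZ1 effect in TPC-1 grew for single genes of several kinds, and no list was tested for this difference. The effect at 72 h exceeded that at 48 h for SERPINB2 by 6.22 ± 0.72 on the log2 scale, TNFAIP6 by 4.48 ± 0.86, the cytokine IL24 by 4.26 ± 0.79, the cyclooxygenase PTGS2 by 3.75 ± 0.59 and IL1A by 3.61 ± 0.86. It became more negative for HLF (-2.92 ± 0.31), SLCO4C1 (-2.77 ± 0.50), PLAC8 (-2.60 ± 0.35), the cadherin CDH6 (-2.56 ± 0.47) and FLG (-2.52 ± 0.23). In limma, 381 genes were called, 175 more positive and 206 more negative at 72 h. The count was 812 and 193 without siNT array 1 or 2 of 48 h, 176 without siCOPZ1 array 3 of 48 h, 253 and 187 without siNT array 2 or 3 of 72 h, 243 and 235 without siCOPZ1 array 2 or 3 of 72 h, and 77 with only these 12 arrays in the fit. With the array number as a block it was 811. IL1A (adjusted p = 0.0320) lost its call without any 1 of 8 of the 12 arrays, with adjusted p up to 0.219 over its alternatives. With only these 12 arrays in the fit TNFAIP6, IL24, PTGS2 and CDH6 lost their calls too (adjusted p = 0.105, 0.0908, 0.0522 and 0.0936). In Nthy-ori 3-1 none of the genes was called in limma, and 1 was called without siNT array 2 of 48 h. At an unadjusted p below 0.05 there were 485, under the share due with no change.

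The lines differed widely before any depletion. With siNT, TPC-1 exceeded Nthy-ori 3-1 in the surface protein TM4SF1 by 7.73 ± 0.14 on the log2 scale, in C14orf105 by 7.41 ± 0.16, in osteopontin (SPP1) by 7.05 ± 0.23, in the growth factor EREG by 6.96 ± 0.18 and in FLG by 6.82 ± 0.12 (SE, 6 wells per line). It was lower in the histone genes HIST1H3I (-8.43 ± 0.14) and HIST1H4L (-7.11 ± 0.25), the fatty acid elongase ELOVL2 (-6.61 ± 0.12), BEX1 (-6.24 ± 0.22) and the RNA-binding protein IGF2BP1 (-5.94 ± 0.21). In limma, 8221 genes were called, 3734 higher and 4487 lower in TPC-1, and 2482 differed at least 2-fold.

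The siNT wells of TPC-1 also changed from 48 h to 72 h, with lower values of proliferation genes. All 49 cell cycle genes were lower at 72 h, with a median of -1.08, and 29 of them were called, among them CDC6 (-1.61 ± 0.31), chosen after its value was seen. With siCOPZ1 the median over the same interval was -0.55 and 3 members were called lower. The inflammatory list had a median of 0.59 with siNT and no called member, against 1.69 and 23 called higher with siCOPZ1. The wells of a group were not alike, since the siNT array numbered 1 had a cell cycle mean of 9.16 at 48 h against 10.2 and 9.94 in the others, and an inflammatory mean of 7.44 against 6.57 and 6.67. At 72 h the cell cycle means of the siCOPZ1 arrays, 9.01 to 9.08, lay within the range of the siNT arrays, 8.35 to 9.25, while the inflammatory means, 9.56 to 9.88, lay above the siNT range of 7.17 to 8.06. In limma, 391 genes were called over time with siNT in TPC-1, 56 higher and 335 lower at 72 h. This count rested on single arrays, as it was 1802, 10 and 47 without siNT array 1, 2 or 3 of 48 h. It was 56 and 30 without siNT array 1 or 3 of 72 h, and 0 with only these 6 arrays. With the array number as a block it was 1128, with all 391 among them. Whether the numbers pair wells across the times was not checked. In Nthy-ori 3-1 with siNT none of the genes was called over time in limma, with 1548 at an unadjusted p below 0.05, and 1 and 35 were called without siNT array 2 of 48 h or of 72 h and 120 with array weights.

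**Figure D4:**
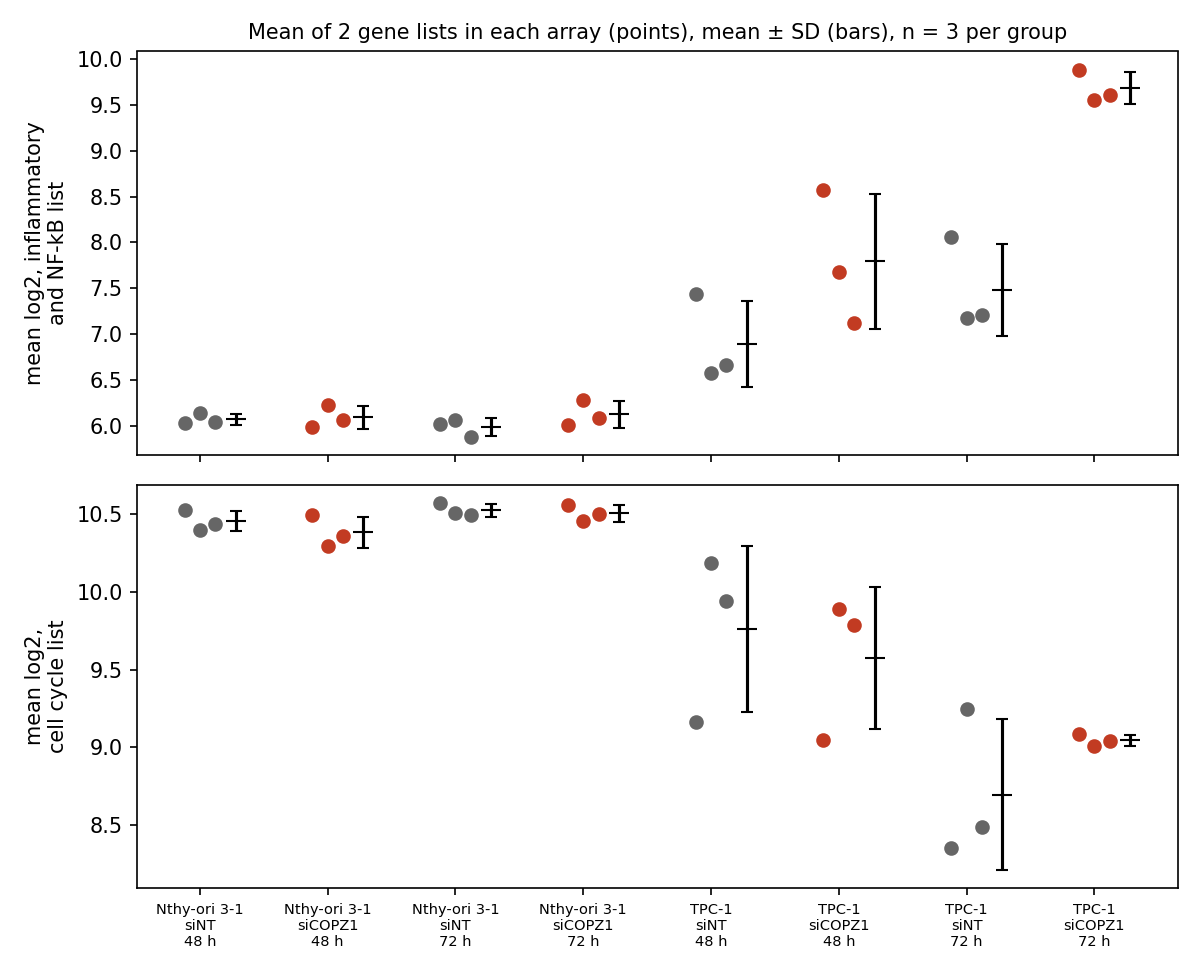
Mean log2 expression of the inflammatory and NF-kB list (34 genes, upper panel) and the cell cycle list (49 genes, lower panel) in each array, with siNT in grey, siCOPZ1 in red and black bars for the mean and standard deviation of 3 wells. In TPC-1 the siNT cell cycle mean drops from 9.76 at 48 h to 8.70 at 72 h, and the siCOPZ1 inflammatory mean is 9.68 at 72 h.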

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

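The test of the spread between wells and the 3 tests of the TPC-1 lists at 72 h were chosen only after the results were seen; the other tests of this part were not. What set the results of this part apart was a tested difference of the siCOPZ1 effect between the lines or between the times.

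Between the lines at 72 h, the named differences reached from cytokine and stress genes to transporters. The effect was more positive in TPC-1 for SERPINB2 (6.92), TNFAIP6 (5.65), BCL2A1 (5.34), IL1A (5.18), MMP1 (4.92), CCL20 (3.97), ALDH1L2 (2.28), STC2 (2.27), CXCL5 (2.00), MMP9 (1.81), DDIT3 (1.52), MANF (1.12) and HSPA5 (0.80), and more negative for SLC14A1 (-4.66), SLCO4C1 (-3.40), HLF (-3.18), CHST9 (-3.11) and FLG (-2.95), on the log2 scale. Among the 7 lists that differed at 72 h were the inflammatory (camera adjusted p = 2.41e-22), endoplasmic reticulum (1.75e-12), integrated stress (9.11e-10), COPI (0.00834), cell cycle (0.000650) and matrix lists (0.0310), all more positive in TPC-1. The remaining list was lipid synthesis (4.64e-05), more negative there. With an estimated correlation only the inflammatory and endoplasmic reticulum lists passed (adjusted p = 0.0290 and 0.00201), and the integrated stress, COPI, cell cycle, matrix and lipid lists did not (adjusted p = 0.161, 0.318, 0.770, 0.542 and 0.405). In limma 749 genes differed, against at most 2 in the other 99 of 100 splits of the arrays, so chance was excluded (1 split of 100 as large, the real one). The DDIT3 call ended without any 1 of 10 of the 12 arrays, and the arrays on which the COPI, cell cycle and matrix calls depend are named in the report.

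At 48 h the inflammatory (adjusted p = 8.76e-12), integrated stress (1.26e-05), endoplasmic reticulum (0.000663) and matrix lists (0.000660) were more positive and lipid synthesis (0.000235) more negative in TPC-1 than in Nthy-ori 3-1. Each of these calls ended with an estimated correlation (adjusted p = 0.161, 0.386, 0.104, 0.318 and 0.462). None of the genes was called in limma (615 at an unadjusted p below 0.05, under the share due with no change). With a real count of 0 all 100 splits are as large by construction, so they decide nothing about chance, and the highest of the others was 1.

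Between the times in TPC-1, the effect differed for 10 named genes, and no list was tested. It was more positive at 72 h for SERPINB2 (6.22), TNFAIP6 (4.48), IL24 (4.26), PTGS2 (3.75) and IL1A (3.61), and more negative for HLF (-2.92), SLCO4C1 (-2.77), PLAC8 (-2.60), CDH6 (-2.56) and FLG (-2.52). In limma 381 genes were called. Of 100 splits that exchange arrays freely 2 were as large, the real one included, which is under the share of 0.05 set for this test. Exchanges that keep arrays of one number together would make only 10 splits, too few for a share under 0.05. Chance therefore stays open where the numbers pair the wells. The other of the 2 called 1070 genes. It exchanged siNT array 1 of 48 h with siNT array 2 of 72 h and siCOPZ1 array 2 of 48 h with siCOPZ1 array 1 of 72 h, which points to a structure of the TPC-1 samples. In Nthy-ori 3-1 limma called 0 genes (485 at an unadjusted p below 0.05, under the share due with no change). All 100 splits are therefore again as large by construction and decide nothing, with 4 as the highest of the others.

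For the other counts the splits say less. Each siCOPZ1 comparison has 10 splits, too few for a share under 0.05. In Nthy-ori 3-1 the real counts were 1 and 1 at 48 h and 72 h, with 0 and 1 as the highest of the other splits. As many genes came from 1 split of the 6 arrays at 48 h and from 2 at 72 h. In TPC-1 they were 31 and 2692, with 3 and 1 as the highest of the others, and 1 split at each time was as large, the real one. At 48 h, where the array numbers pair the TPC-1 wells, the other splits that part all 3 pairs gave 0 genes, and those that part fewer gave up to 3. For siNT over time the splits were again too few. In Nthy-ori 3-1 the real count was 0 (1548 at an unadjusted p below 0.05 in limma), which all 10 reach by construction, with a highest of 0. In TPC-1 the real count was 391, and 2 of the 10 splits were as large. The highest other gave 514 and exchanged siNT array 1 of 48 h with siNT array 2 of 72 h, the same structure as above. Between the lines with siNT the real split gave 8221 genes and the highest of the other 99 gave 6475. Only the real split of the 100 was as large, a share under 0.05, but this holds for free exchanges of arrays alone.

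COPZ1 loss was followed by 2692 called genes in TPC-1 and by COPZ1 alone in Nthy-ori 3-1 at 72 h. The wells of Nthy-ori 3-1 did not have a larger spread, since its median residual standard deviation was 0.823 times that of TPC-1. This ratio does not test the counts, because the fit gave both lines the same spread per gene. The median standard error at 72 h was 0.191 in both lines. The shared spread may be too wide for Nthy-ori 3-1 and so hide changes there. With only the arrays of a comparison in the fit, the counts at 72 h were 0 in Nthy-ori 3-1 and 1507 in TPC-1. A weaker knockdown in Nthy-ori 3-1 cannot be told apart from a line-specific response. The 95% interval of the difference in COPZ1 change at 72 h reached from -1.26 to 0.0703 and so held both 0 and a sizeable gap. At 48 h COPZ1 with siCOPZ1 stood at 25.8% of siNT in Nthy-ori 3-1 and at 10.5% in TPC-1. The 95% interval of that earlier difference excluded 0, although it did not pass adjustment over all genes. The deepest knockdown of all, in TPC-1 at 48 h, went with only 31 called genes, so depth alone did not set the count, although 48 h and 72 h may differ in how far the effects had developed. A biological difference between normal and carcinoma-derived cells stays open and untested, as does the culture medium, which differs between the lines.

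Interferon-stimulated genes, with IFIT3 at 0.98 and IFIT1 at -1.04 on the log2 scale, gave no shared direction in TPC-1 at 72 h. A pool of enzymatically cut duplexes could raise such genes early, but the median of the list was 0.0452 at 48 h, below its value of 0.09 at 72 h, and neither bound set for this test was met, so the kind of reagent cannot be told apart from the depletion. Other cells mixed in were checked with 29 markers, whose median at 72 h was -0.0812, with CD14 at -0.51 and PDGFRB at -1.50 called lower (these and IFIT3 chosen after their values were seen). This lies within the bound written for no mixture, yet that bound was the wrong one, as the interferon genes themselves move both ways and a median near 0 decides nothing. Scaling moved the median of the list by 0.0564, which also decides nothing for so small a median.

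In TPC-1 at 72 h the inflammatory list, with CXCL8 (4.28) and IL6 (2.89) chosen after their values were seen, and the cell cycle list were both called higher with siCOPZ1 than with siNT. The cell cycle call, with 4 of 49 members called, ended with an estimated correlation (adjusted p = 0.770) and without siNT array 1 (0.107), so that pattern is itself uncertain. For the inflammatory list a fall of the controls was argued against, since its median went up by 0.590 from 48 h to 72 h with siNT, with no member called, and by 0.264 without siNT array 1 of 72 h, the lowest of the runs without 1 array. For the cell cycle list a fall of the controls is a candidate explanation, with a median of -1.08 over the same interval and -0.85 to -1.40 without any 1 of the 6 arrays, so the difference at 72 h may reflect controls that slowed rather than depleted cells that divided. For the inflammatory list the kind of reagent stays open beside a response to COPZ1 loss, since its median in Nthy-ori 3-1 at 72 h was 0.133 with the same duplexes, but the lines may take up or sense RNA differently.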

How the results depend on the processing

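The fit without the arrays numbered 1 was chosen after seeing the data, because those arrays had the lowest score of each TPC-1 group on a principal component, and all other alternatives were planned. The count for siCOPZ1 in TPC-1 at 72 h stayed within 1.5-fold of 2692 except in 2 cases, at 1507 with only the 6 arrays of that comparison and 887 when a change of at least 1 on the log2 scale was also asked for. Quantile normalisation, median centring and averaging of repeated symbols moved none of the 11 counts by more than 1.5-fold.

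The mean-variance trend with robust moderation gave 60 genes for siCOPZ1 in TPC-1 at 48 h in place of 31. With only the arrays of a comparison, COPZ1 lost its call in Nthy-ori 3-1 at differences of -1.96 and -1.57, leaving 0 genes at 48 h and 0 at 72 h in limma (906 and 574 at an unadjusted p below 0.05 with all arrays). The same fits gave 1 gene in TPC-1 at 48 h, 77 for the time difference in TPC-1 and 0 for siNT over time in TPC-1. These fits estimate the spread from fewer arrays by construction. Array weights gave 3 genes in Nthy-ori 3-1 and 66 in TPC-1 at 48 h, 1210 for the line difference at 72 h, and 120 and 986 for siNT over time in Nthy-ori 3-1 and TPC-1. Leaving out the dimmest tertile gave 56 genes in TPC-1 at 48 h and 603 for siNT over time in TPC-1. Blocking on the array number gave 2 genes at each time in Nthy-ori 3-1, 78 in TPC-1 at 48 h, 1303 for the line difference at 72 h, 811 for the time difference in TPC-1, and 54 and 1128 for siNT over time in Nthy-ori 3-1 and TPC-1. The block changed the call of 1 named gene and of none of the lists for siCOPZ1 in TPC-1 at 48 h. In all 12 pairs of arrays of one number the correlation exceeded that with other numbers, a hint from the data and not from the design. Apart from the fewer arrays and the stricter thresholds, the cause was not tested.

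The threshold of 2-fold, stricter by construction, left 14 genes in TPC-1 at 48 h, 2482 between the lines with siNT and 186 for siNT over time in TPC-1. At an adjusted p below 0.01 the lines shared 0 genes at 72 h in limma, since COPZ1 fails that level in Nthy-ori 3-1. Without the arrays numbered 1 there were 3 genes in TPC-1 at 48 h, 442 for the line difference at 72 h, 1 and 844 for siNT over time in Nthy-ori 3-1 and TPC-1, and the interferon-stimulated list passed in Nthy-ori 3-1 at 72 h (adjusted p = 0.0158).

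Leaving out each array in turn gave 0 to 1 gene for siCOPZ1 in Nthy-ori 3-1 at 72 h and 6 to 38 in TPC-1 at 48 h. In the Nthy-ori 3-1 runs COPZ1 lay between -1.43 and -1.74 and was called only without siCOPZ1 array 1 (limma adjusted p = 0.0193). The gene called without siNT array 3 was another one, since COPZ1 had an adjusted p of 0.0928 there. The line difference gave 0 to 7 genes at 48 h and 485 to 791 at 72 h, and the time difference 0 to 1 in Nthy-ori 3-1 and 176 to 812 in TPC-1. For siNT over time the range was 0 to 35 in Nthy-ori 3-1 and 10 to 1802 in TPC-1. The adjusted p of the interferon-stimulated list ranged from 0.0129 to 0.928 in Nthy-ori 3-1 at 72 h and from 0.0387 to 0.383 in TPC-1 at 48 h. Lists reversed in 3 results, with adjusted p from 1.49e-12 to 0.646 for the integrated stress response in Nthy-ori 3-1 at 72 h, from 4.49e-15 to 0.802 for the cell cycle in TPC-1 at 48 h, and from 5.23e-12 to 0.723 for the cell cycle in the line difference at 48 h. In the last of these the list turned up without TPC-1 siCOPZ1 array 1 (adjusted p = 0.0456), and the other arrays are named in the report. The cause was not tested.

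The named genes, without COPZ1 in the siCOPZ1 comparisons, whose lost calls are given apart, have 2504 values under the alternatives, of which 2412 kept their side of the threshold, 86 lost the call and 6 gained it. Of the 2412, 43 uncalled values changed sign, and 0 called values did. Of 90 list results, an estimated correlation ended 22 calls, fry ended 15 and added 3, quantile normalisation changed none, blocking added 5, the dim genes left out ended 2 and added 4, and the fit without the arrays numbered 1 ended 4 and added 9. Of the alternatives set out at the start 2 were not run, a background correction from scanner files, which were not used here, and a block on batches, since the labels give none and the structure by array number entered through the block on that number. Signal over background limits the dim genes, whose changes RMA compresses, so absence of a call for IFNB1, with group means of 3.59 to 3.98, carries little weight. CXCL10, like IFNB1, fell in the dimmest tertile of genes, so its lack of a call is limited in the same way.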

Other observations

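The only test of this part, of the genes that set the lines apart, was chosen after other results were seen, though its prediction was written before its own result, and the genes named here were chosen after their values were seen. In TPC-1 at 72 h the genes of the checkpoint ligands PDCD1LG2 (2.22) and CD274 (1.58) and of the peptide transporter TAP2 (0.87) rose on the log2 scale. The thyroid hormone receptor THRB (-2.09) and the thyroid transcription factor FOXE1 (-0.90) fell. So did the matrix-associated CTGF (-1.67) and THBS1 (-1.54), the anti-apoptotic BCL2 (-1.01) and the pro-apoptotic BCL2L11 (-1.20), while the NF-kB inhibitor TNFAIP3 (3.49), the stress sensor ERN1 (2.00) and its target XBP1 (0.92) rose.

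Among the 1382 called falls in TPC-1 at 72 h, 6 more genes are given singly, without a list test. IGFBP3, which binds insulin-like growth factors, fell by 3.05 on the log2 scale. Its relative IGFBP5 fell by 2.73. The growth factor TGFB2 fell by 3.00, and the receptor FGFR4 fell by 2.66. The phosphate transporters SLC17A1 and SLC17A3 fell by 2.57 and 2.34. The urea transporter SLC14A1, lower with siCOPZ1, was also higher at 72 h than at 48 h with siNT by 2.63 (limma adjusted p = 0.0485). That comparison called 391 genes, and between 10 and 56 without siNT array 2 or 3 of 48 h or siNT array 1 or 3 of 72 h.

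FLG was among the largest excesses of TPC-1 over Nthy-ori 3-1 and among its largest falls after siCOPZ1, which prompted the hypothesis that depletion lowers genes that set TPC-1 apart. Of 1103 genes called at least 2-fold higher in TPC-1 from the siNT means of 48 h, 323, or 29.3%, were called lower after siCOPZ1 at 72 h. The means of these calls share no array, but both took the spread of each gene from all 24 arrays. Genes of small spread are thus favoured in both calls. In 10000 random lists matched on level, but not on spread, the median was 8.52% (95% range 6.98 to 10.2), and the share lay above all 10000. Of the same genes 9.70% were called higher, against 10.1% in the matched lists. Of 888 genes higher in Nthy-ori 3-1, 12.3% were called higher in TPC-1 after siCOPZ1 against 6.76%, and 6.76% called lower against 7.32%. Depletion may thus move TPC-1 away from its own profile, as a hypothesis found and tested on the same arrays, with genes that are not independent of each other.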
